A study of Mus musculus with 4 samples.

How the data were processed

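Bulk RNA sequencing of mouse liver was analysed for 4 libraries, 2 from mice with a liver-specific knockout of Marchf6 and 2 from littermate controls, all collected after an overnight fast and 4 h of refeeding. Libraries are named here by genotype and by the number in their labels (control 3, control 4, knockout 3 and knockout 4). Nothing beyond the labels states that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

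The deposited values are raw counts per gene, 1 column per library, with no normalization and no pooling, per the file headers. Total RNA was extracted with TRIzol and libraries were made with a directional (strand-marking) kit, per the labels' protocols. Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 and the mouse build GRCm38 are named per the submitters' processing notes, without roles or settings. The strand setting of the counting and the annotation release are not given in the sources used here, so reads from overlapping genes on opposite strands may not be separable. How reads matching several places were counted is not given either, so genes with near-identical copies are uncertain, among them the Mup family, Cyp2a4 beside Cyp2a5, Cyp2b9 beside Cyp2b13, and mitochondrial genes with copies in the nuclear genome.

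The files held 49315 genes, of which 49056 were found in a GENCODE annotation of GRCm38 and 48970 were given a symbol there. Marchf6 stands in that annotation under its older symbol March6, which is used below. All 49056 lay on the same chromosome in both, and coordinates below are from that annotation. The 4 single-library tables and the table of the whole series differed in 0 cells, 0 lines named no gene, and no column of values per sample was left unused. Total counts were 19473107 in control 3, 17274435 in control 4, 19808691 in knockout 3 and 21697665 in knockout 4. No pair of libraries was alike within sampling noise, since the chi-square statistic per degree of freedom over genes ranged from 40.5 to 165.

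Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, estimateDisp, glmQLFit and glmQLFTest with group as the only term, two-sided, and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. Standard errors came from the F statistic and the fitted log2 fold change, and intervals are at 95%. Values are CPM, counts scaled to a common library size after TMM adjustment, given as mean ± SD over the 2 libraries of a group. With 2 libraries against 2, an exact two-sided permutation test cannot give a p under 0.333, so single values were not tested that way.

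Before the data were examined, 47 gene lists (pathways, zonation, sex-biased genes, cell type markers and RNA quality) were fixed, with 968 of 970 members found in the files. The 44 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Members past the gene test were counted over all genes and adjusted over the list alone. Camera with an estimated correlation, and fry, a rotation test of whether a list moves one way, were alternatives. The design, the alternatives and the rule for naming genes were also fixed before the data were examined. That rule takes March6 and a fixed list of study genes. Some genes that the rule names are not reported here. It then takes up to 12 genes with the largest rise and up to 12 with the largest fall past the threshold, with a mean of at least 2 CPM in the higher group, both libraries of one group above both of the other, and a named symbol. It adds up to 4 members with the smallest p of each list called or holding at least 3 called members, and the sex-linked genes. Genes called by DESeq2 and not by edgeR, or called only when adjusted over a list alone, were chosen after their values were seen, as were single genes given as examples of differences between libraries. Lists of markers of brain neurons, astrocytes, oligodendrocytes, peripheral nerve, and pancreatic islet and neuroendocrine cells were written after neuronal genes had been seen among the genes lower in knockout. Folds over summed marker counts carry 95% exact binomial intervals, and these and the floor of 3 counts over a group cover counting error only.

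Alternatives were no low-count filter, a filter of at least 50 counts in at least 2 libraries, DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0, limma-voom, the library number as a block, leaving out each library in turn, edgeR glmTreat at a fold of 1.5, leaving out X and Y genes, the series-wide table, and list members that stand in no other list. A non-legacy and a robust edgeR fit were added after seeing the data.

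The tests were run first on simulated data with the means and library sizes of these 4 libraries (14366 genes tested, knockout against control). edgeR called 93% of 100 genes changed 4-fold and 21% of 100 genes changed 2-fold, with 15 unchanged genes called. DESeq2 called 93% and 31%, with 22 unchanged genes called. Camera called 5 of 5 lists shifted by 0.5 on the log2 scale and 0 of 44 unshifted lists with the preset correlation, and 0 of the 5 shifted lists with an estimated one. A list not called with an estimated correlation may therefore still have moved. The simulated genes varied independently of each other, unlike genes in tissue. The shares called in the simulation need not hold in the data, where edgeR called 2 genes. Rgs16 at 7.15-fold, Mfsd2a at 4.21-fold and Cyp2b9 at 9.19-fold were not called there (edgeR adjusted p = 0.0519, 0.102 and 0.236).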

Results

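Liver messenger RNA was counted in 4 libraries of mice that had been fasted overnight and refed for 4 h. Mice lacking Marchf6 in the liver (2 libraries) were compared with littermate controls (2 libraries). Marchf6 is a ubiquitin ligase of the endoplasmic reticulum that takes part in ER-associated degradation, and the study's title places it in hepatic lipid metabolism and fatty liver disease. Library totals ranged from 17274435 to 21697665 counts, and 14724 genes were tested. Genes of the mitochondrial genome took 19.5% of counts in control 3, 12.6% in control 4, 16.5% in knockout 3 and 28.3% in knockout 4. The first principal component held 47.1% of the variance and separated the libraries numbered 3 from those numbered 4. The second held 34.2% and separated knockout from control.

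The targeted gene, March6 (ENSMUSG00000039100, chromosome 15, 31455899 to 31531037 on the minus strand of GRCm38), was counted lower in both libraries labelled knockout. Its level was 77.6 ± 1.91 CPM in control (SD, n = 2) and 26.3 ± 3.27 CPM in knockout (SD, n = 2), from 1435 and 1459 counts against 463 and 612. The log2 fold change was -1.56 ± 0.24 (SE), 0.338 of the control level. The edgeR test gave an unadjusted p of 0.00019 and an adjusted p of 0.23, and DESeq2 gave an adjusted p of 0.000128. The deleted exons are not stated in the sources used here, and the counts cover the whole gene.

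Cyp2a4 and Pnpla3 were the genes that edgeR called higher in knockout liver. Cyp2a4, a female-biased hepatic cytochrome P450, rose 18.6-fold, from 4.80 ± 0.659 to 89.5 ± 13.7 CPM (SD, n = 2 each; log2 fold change 4.22 ± 0.28 SE, edgeR adjusted p = 0.00637). Pnpla3, a lipid droplet protein whose human form is tied to fatty liver disease, rose 12.8-fold, from 1.42 ± 0.171 to 18.3 ± 0.872 CPM (SD, n = 2 each; log2 fold change 3.68 ± 0.29 SE, edgeR adjusted p = 0.01). Cyp2a4 (ENSMUSG00000074254) lies on chromosome 7 from 26307169 to 26315088, and Pnpla3 (ENSMUSG00000041653) on chromosome 15 from 84167816 to 84189512. Cyp2a4 is nearly identical to Cyp2a5, which had 1067 ± 490 CPM in control and 1260 ± 257 CPM in knockout, so reads may have been split between them. edgeR called 2 genes higher and 0 lower, with 242 higher and 214 lower at an unadjusted p under 0.05. Together these were 456 of 14724 genes, a smaller share than the 0.05 that tests without any difference would give. DESeq2 called 23 higher and 19 lower, and limma-voom 3 higher and 0 lower. Both knockout libraries lay above both control libraries for 12.4% of genes and below them for 13.5%, where chance gives 16.7% for each. The count depended on single libraries: edgeR called 98 genes without control 3, 91 without control 4, 40 without knockout 3 and 6 without knockout 4, each time with Cyp2a4 and Pnpla3 among them.

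Several other genes passed DESeq2's test but not edgeR's. Rgs16, a regulator of G protein signalling that responds to feeding in liver, had 18 ± 5.08 CPM in control and 129 ± 2.07 CPM in knockout (SD, n = 2 each; log2 fold change 2.84 ± 0.30 SE, edgeR adjusted p = 0.0519, DESeq2 adjusted p = 2.2e-16). Mfsd2a, a lysophospholipid transporter, had 8.55 ± 1.14 against 36 ± 5.9 CPM (edgeR adjusted p = 0.102, DESeq2 adjusted p = 5.9e-07). Derl3, a Derlin of the ER-associated degradation machinery, had 10.4 ± 2.29 against 56.1 ± 28.6 CPM (edgeR adjusted p = 0.236, DESeq2 adjusted p = 7.6e-07). The glucose-responsive gene Txnip was 2.61 times and the mitochondrial carrier gene Slc25a47 2.75 times the control level, both called by DESeq2 alone (adjusted p = 0.0011 and 0.000129). Of the 4 edgeR fits without 1 library, Rgs16 and Mfsd2a were called in 4, Derl3 in 3 and Txnip and Slc25a47 in 0. Among genes that DESeq2 called lower, Apoa4, an apolipoprotein, was at 0.356 of control (DESeq2 adjusted p = 0.00671, edgeR adjusted p = 0.866) and the glutathione transferase gene Gstp1 at 0.398 (DESeq2 adjusted p = 0.00112, edgeR adjusted p = 0.549). Exons of Apoa4 overlapped genes on the opposite strand over 69.8% of their length, those of Rgs16 over 10.1% and those of Txnip over 19.4%, and the strand setting of the counting is not given.

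DESeq2 also called lower some genes known from nervous tissue, for which no list had been fixed and no enrichment was tested. Camk2a, a neuronal kinase, had 101 and 63 counts in the control libraries and 2 and 3 in the knockout libraries (DESeq2 adjusted p = 4.3e-06, edgeR adjusted p = 0.0519). Snap25, a synaptic vesicle fusion protein, had 65 and 40 counts against 2 and 0. The dendritic gene Ddn, with 33 and 42 counts in control and 0 in both knockout libraries, was at least 27.3-fold lower, and Hpcal4, a neuronal calcium sensor, at least 21.1-fold lower, against a floor of 3 counts over the group. Over a list of 24 markers of brain neurons, written after these genes had been seen, 24 had a higher mean CPM in control, and for 16 (66.7%) both control libraries lay above both knockout libraries, where chance gives 16.7% of genes not picked for the change. Their summed counts were 1.49 times as high in control (95% interval 1.41 to 1.57, counting error only). The sums were 1869 and 1418 counts in control and 1101 and 1313 in knockout, of which Ppp3ca alone gave 802 and 657 against 752 and 769. The ratio is thus set largely by genes well counted in all 4 libraries, and not by those nearly missing from knockout. Other markers of that list were also counted in all 4 libraries, such as Nrgn with 58 and 37 counts in control and 52 and 44 in knockout and Thy1 with 43 and 39 against 48 and 34.

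**Figure D1:**
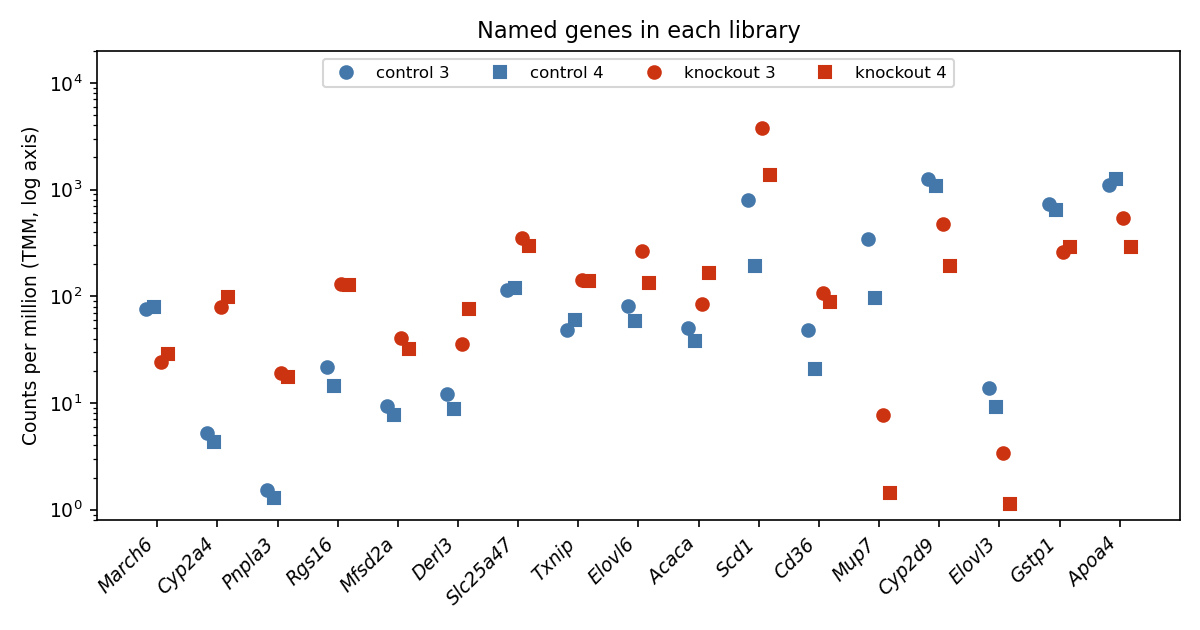
CPM (TMM-scaled, log axis) of 17 named genes in each of the 4 libraries; each point is 1 library, blue for control and red for knockout, circles for number 3 and squares for number 4, with no error bars. Cyp2a4 stood at 5.26 and 4.33 CPM in control and 79.8 and 99.1 CPM in knockout, while March6 stood at 76.3 and 79 against 24 and 28.6 CPM.

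Genes that are higher in male than in female mouse liver were called lower as a list in the knockout, and genes higher in female liver were called higher as a list. The log2 fold change was below 0 for 17 of 17 male-biased genes, with a median of -1.46, and the list was called lower by camera (adjusted p = 1.4e-15; adjusted p = 0.781 with an estimated correlation). Mup7, a major urinary protein, had 219 ± 174 CPM in control and 4.6 ± 4.46 CPM in knockout (SD, n = 2 each). Elovl3, a fatty acid elongase, was at 0.193 of the control level (log2 fold change -2.37 ± 0.49 SE) and Cyp2d9, a steroid-metabolising cytochrome P450, at 0.29 (log2 fold change -1.79 ± 0.46 SE). Of the 17 male-biased genes, 0 passed edgeR's test over all genes, and 5 passed when adjusted over the list alone (Mup7, Cyp2d9, Elovl3, Serpina1e and Gstp1); 9 were lower at an unadjusted p under 0.05, and DESeq2 called 4 of them. The female-biased list was called higher (median log2 fold change 1.25, 12 of 14 members above 0, camera adjusted p = 2.6e-07; adjusted p = 0.781 with an estimated correlation). Of its 14 members edgeR called 1 over all genes, Cyp2a4, and 4 when adjusted over the list alone, namely Cyp2a4, Cyp2b9, Cyp2b13 and Cyp2a22, and DESeq2 called 4 over all genes. Cyp2b9 had 69.2 ± 19.5 against 636 ± 410 CPM, and Cyp2a22 108 ± 19.2 against 585 ± 430 CPM. Without 1 library, the log2 fold change of Cyp2a22 ranged from 1.389 to 3.06 and that of Mup7 from -7.217 to -4.379. That of Elovl3 ranged from -3.342 to -1.773, that of Cyp2d9 from -2.579 to -1.27 and that of Cyp2b9 from 2.326 to 3.757. Both lists were called without each of the 4 libraries in turn, with the male-biased median at -0.7938 without control 3, -1.889 without control 4, -3.406 without knockout 3 and -0.9856 without knockout 4, and the female-biased median from 1.297 to 1.796. The sex-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 222 and 184 CPM in control and 185 and 198 CPM in knockout, and Xist had between 2 and 6 counts in each library.

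Fatty acid synthesis genes were called higher as a list in the knockout. The log2 fold change was above 0 for 18 of 21 members, with a median of 0.32 (camera adjusted p = 0.000214; adjusted p = 0.781 with an estimated correlation). Pnpla3 was the member that edgeR called over all genes, where DESeq2 called 3 higher and 1 lower, while adjusted over the list alone edgeR called 5 higher (Pnpla3, Acaca, Elovl6, Scd1 and Thrsp) and 1 lower (Elovl3). Scd1, the stearoyl-CoA desaturase, had 492 ± 424 CPM in control and 2596 ± 1719 CPM in knockout (SD, n = 2 each; log2 fold change 2.40 ± 0.73 SE), which did not pass over all genes. Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, was at 2.83 times control (log2 fold change 1.502 ± 0.36 SE, edgeR adjusted p = 0.622, DESeq2 adjusted p = 0.012), and the elongase Elovl6 at 2.86 times (DESeq2 adjusted p = 0.0118). Fasn, the fatty acid synthase, had 296 ± 50.2 against 371 ± 9.17 CPM (log2 fold change 0.32 ± 0.29 SE). Srebf1, the transcription factor gene of lipogenesis, had 71.6 and 85.9 CPM in control and 82.5 and 235 CPM in knockout. The call of the list was lost without knockout 3 (adjusted p = 0.24, median 0.15). Without 1 library, the log2 fold changes ranged from 1.504 to 3.762 for Scd1 (called in 1 of the 4 fits), from 0.9422 to 1.921 for Acaca (called in 1), from 0.958 to 1.927 for Elovl6, from 0.1628 to 0.5253 for Fasn and from 0.0726 to 1.591 for Srebf1.

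Among the fixed lists of fatty acid uptake, storage, secretion and oxidation, edgeR called 0 genes, and DESeq2 called Cd36 higher and Apoa4 lower. Cd36, a fatty acid transporter, had 34.7 ± 19.9 CPM in control and 97.4 ± 13.9 CPM in knockout (edgeR adjusted p = 0.883, DESeq2 adjusted p = 0.0419). Fgf21, a hepatic hormone of nutrient stress, had 2.63 ± 0.413 against 9.1 ± 5.7 CPM (log2 fold change 1.79 ± 0.46 SE, edgeR adjusted p = 0.825), with 5.07 CPM in knockout 3 and 13.1 CPM in knockout 4. Without 1 library, the log2 fold change of Fgf21 ranged from 0.9497 (without knockout 4) to 2.331 (without knockout 3), called in 2 of the 4 fits, and that of Cd36 from 1.016 to 2.241, called in 1. The log2 fold changes were 0.025 ± 0.37 (SE) for the triglyceride synthesis gene Dgat2, 0.18 ± 0.34 for the lipid droplet gene Plin2, -0.053 ± 0.28 for Mttp and -0.29 ± 0.39 for Apob, both of lipoprotein assembly. For Ppara and Cpt1a, of fatty acid oxidation, they were -0.26 ± 0.23 and -0.21 ± 0.31, and none of these 6 genes passed edgeR's or DESeq2's test. Without 1 library, the log2 fold change of Apob ranged from -0.6017 to -0.01878. Camera called none of the lists of triglyceride synthesis and lipid droplets (24 genes, adjusted p = 0.992), fatty acid oxidation (30 genes, adjusted p = 0.335), fatty acid uptake (16 genes, adjusted p = 0.129) or lipoprotein assembly (20 genes, adjusted p = 0.213).

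Cholesterol synthesis genes were called lower as a list, and none of the 20 members passed the test alone. The log2 fold change was below 0 for 19 of 20 members, with a median of -0.42 (camera adjusted p = 0.00392; adjusted p = 0.825 with an estimated correlation). Sqle, the squalene epoxidase and a known substrate of Marchf6, had 62.3 ± 43.9 CPM in control and 38.9 ± 37.6 CPM in knockout (SD, n = 2 each; log2 fold change -0.68 ± 0.73 SE). Hmgcs1, an early enzyme of the pathway, had 234 ± 160 against 162 ± 107 CPM. The sterol feedback gene Insig1 and the SREBP2 gene Srebf2 gave log2 fold changes of -0.82 ± 0.52 and -0.37 ± 0.28 (SE), and neither passed. Without 1 library, Insig1 ranged from -1.738 (without knockout 3) to -0.2303 (without control 3) and Srebf2 from -0.6566 to -0.1082 (the same libraries). Of these 20 members, 0 were called over all genes by edgeR or DESeq2 and 0 adjusted over the list alone, and for 0 did the knockout pair lie apart from the control pair. In both groups 20 of 20 were higher in the library numbered 3 than in the one numbered 4, by a median log2 difference of 1.26 in control and 1.36 in knockout. With a split this wide, the groups can overlap even where they differ within each number. With the library number as a block and the preset correlation, the median was -0.4792 and the list was called (camera adjusted p = 7.506e-08). No label says what the number marks. Leaving out 1 library makes the numbers uneven between the groups, so part of the difference between the numbers enters the fold changes of such fits. Without control 3 the median log2 fold change of the list was 0.17 and without knockout 4 it was 0.0742, and the call was lost (adjusted p = 0.745 and 0.243). Without control 4 it was -0.9025 and without knockout 3 -1.309, and the list was called.

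**Figure D2:**
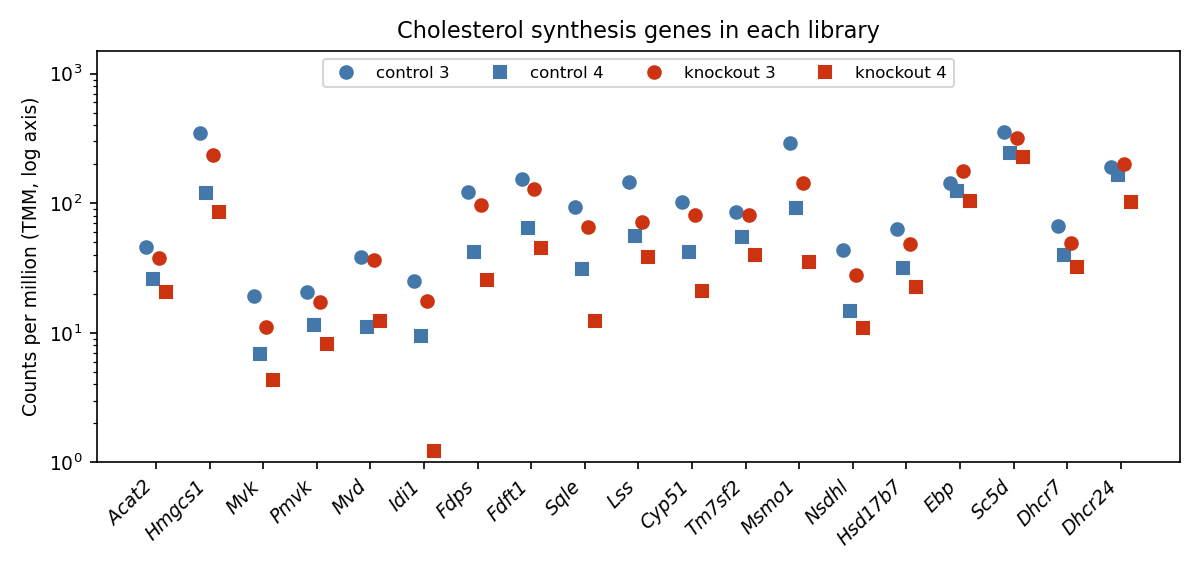
CPM (TMM-scaled, log axis) of 19 of the 20 cholesterol synthesis genes in each of the 4 libraries; each point is 1 library, blue for control and red for knockout, circles for number 3 and squares for number 4. In each group every plotted gene was higher in the library numbered 3, and for none did the groups separate.

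Chaperone and stress genes of the endoplasmic reticulum had small log2 fold changes. The unfolded protein response list was called higher with a median log2 fold change of 0.21, and 17 of 23 members were above 0 (camera adjusted p = 0.0345; adjusted p = 0.825 with an estimated correlation). Hspa5, the main ER chaperone, had 1460 ± 107 CPM in control and 1684 ± 407 CPM in knockout (log2 fold change 0.21 ± 0.36 SE), and Ddit3, a stress-induced transcription factor gene, 33.6 ± 15.9 against 34.4 ± 6.85 CPM (log2 fold change 0.033 ± 0.35 SE). Creld2 and Wfs1 had log2 fold changes of 0.49 ± 0.28 and 0.42 ± 0.24 (SE). Of the 23 members, 0 passed edgeR's or DESeq2's test over all genes and 0 edgeR's adjusted over the list alone. The 41 genes of ER-associated degradation were not called as a list (median log2 fold change -0.05, camera adjusted p = 0.744), with Derl3 the 1 member that edgeR called when adjusted over the list alone and DESeq2 called over all genes, where edgeR called 0. The integrated stress response list was not called either (18 genes, median 0.07, camera adjusted p = 0.111). The call of the unfolded protein response was lost without control 3 (adjusted p = 0.371, median 0.13), control 4 (adjusted p = 0.181) or knockout 3 (adjusted p = 0.771, median 0.0237) and with the library number as a block (adjusted p = 0.0586). Without knockout 4 the median was 0.32.

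Matrix genes and markers of non-parenchymal cells were called higher as lists. For fibrosis and extracellular matrix, 20 of 22 members had a log2 fold change above 0, with a median of 0.66 (camera adjusted p = 1.7e-08; adjusted p = 0.781 with an estimated correlation). Col1a1, a chain of type I collagen, had 4.62 ± 1.43 CPM in control and 12.3 ± 3.73 CPM in knockout, and Spp1, osteopontin, 25.7 ± 0.391 against 72 ± 36.3 CPM (SD, n = 2 each). These 2 passed edgeR's test when adjusted over the list alone. Over all genes 0 of 22 passed with edgeR and 1, Spp1, with DESeq2 (adjusted p = 0.022), and the list was called without each library in turn, with a median of 0.3937 without control 3, 1.015 without control 4, 0.7109 without knockout 3 and 0.436 without knockout 4. In the same libraries the medians of cell type markers were 0.73 for cholangiocytes (11 genes, camera adjusted p = 0.00232), 0.52 for mesothelial and smooth muscle cells (8 genes, adjusted p = 0.00232), 0.33 for stellate cells (15 genes, adjusted p = 0.00204) and -0.22 for hepatocytes (15 genes, adjusted p = 0.0499). With an estimated correlation the adjusted p was 0.781 for the first 3 and 0.825 for hepatocytes. Over all genes 0 of these markers passed with edgeR and 1 with DESeq2, Spp1 among the cholangiocyte markers, which was also the 1 that passed edgeR's test adjusted over the list alone. Without 1 library its log2 fold change ranged from 0.8542 to 1.939. Epcam and Krt19, of cholangiocytes, had log2 fold changes of 1.43 ± 0.56 (from 0.9432 to 2.096 without 1 library) and 1.13 ± 0.42 (SE) at levels below 3 CPM, and Lrat, of stellate cells, 0.45 ± 0.24. Lists of endothelial, Kupffer cell and lymphocyte markers were not called (adjusted p = 0.313, 0.967 and 0.156). The cholangiocyte call was lost without knockout 4 (adjusted p = 0.497, median -0.10) and with the filter of at least 50 counts (7 members, adjusted p = 0.0719, median 0.14), and the median was 1.212 without knockout 3. The stellate call was lost without knockout 3 (adjusted p = 0.0607) or control 3 (adjusted p = 0.629, median 0.15), and the median was 0.61 without control 4. The mesothelial call was lost without knockout 3 (adjusted p = 0.222, median 0.0717), and the median was 1.032 without knockout 4. The hepatocyte call was lost without control 3, control 4 or knockout 4 (adjusted p = 0.135, 0.257 and 0.855, the last with a median of -0.0188), with DESeq2 size factors (adjusted p = 0.0509), with the library number as a block (adjusted p = 0.0615), with members in no other list (adjusted p = 0.361) and with no low-count filter (adjusted p = 0.195), and the median was -0.52 without knockout 3.

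Immune and immediate early genes were called higher as lists with small shifts. The interferon response had a median log2 fold change of 0.31 (24 genes, 20 above 0, camera adjusted p = 0.000214), the acute phase response 0.12 (24 genes, 19 above 0, adjusted p = 0.0273) and inflammatory cytokines 0.22 (17 genes, 13 above 0, adjusted p = 0.0208). Each had an adjusted p of 0.781 with an estimated correlation. Gbp3 and Oasl2, of the interferon response, had log2 fold changes of 0.69 ± 0.27 and 0.70 ± 0.30 (SE), and Saa2, an acute phase protein, 1.44 ± 0.39. Immediate early and heat shock genes had a median of 0.25 (17 genes, adjusted p = 0.0238; adjusted p = 0.825 with an estimated correlation), with Fos at 1.29 ± 1 CPM in control and 11.2 ± 13.6 CPM in knockout. The 13 mitochondrial messenger RNAs had a median of 0.50 (adjusted p = 0.000214; adjusted p = 0.825 with an estimated correlation). In these 5 lists, edgeR called 0 members over all genes and 0 adjusted over the list alone, and DESeq2 called 1, Dusp1 of the immediate early list (adjusted p = 0.0269). Without 1 library, the log2 fold change of Fos ranged from 0.3108 to 4.259 (called in 2 of the 4 fits), that of Saa2 from 0.7405 to 1.928 (called in 1), that of Gbp3 from 0.442 to 0.9165 and that of Oasl2 from 0.421 to 1.054. Calls were lost without control 4 for the interferon, acute phase, cytokine and mitochondrial lists (adjusted p = 0.295, 0.13, 0.568 and 0.438) and without control 3 for the acute phase and immediate early lists (adjusted p = 0.0545 and 0.479). They were also lost without knockout 3 for the interferon, cytokine and immediate early lists (adjusted p = 0.146, 0.122 and 0.573, the last with a median of -0.17) and without knockout 4 for the acute phase, cytokine and mitochondrial lists (adjusted p = 0.132, 0.0737 and 0.365). With the filter of at least 50 counts the cytokine and immediate early calls were lost (adjusted p = 0.127 and 0.0752). Leaving out control 3, control 4, knockout 3 and knockout 4 in turn gave medians of 0.54, 0.22, 0.17 and 0.46 for the interferon list, 0.0615, 0.17, 0.19 and 0.0866 for the acute phase list, 0.38, 0.13, 0.22 and 0.22 for the cytokine list, 0.97, 0.19, 0.79 and 0.11 for the mitochondrial list and 0.18, 0.53, -0.17 and 0.57 for the immediate early list.

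**Figure D3:**
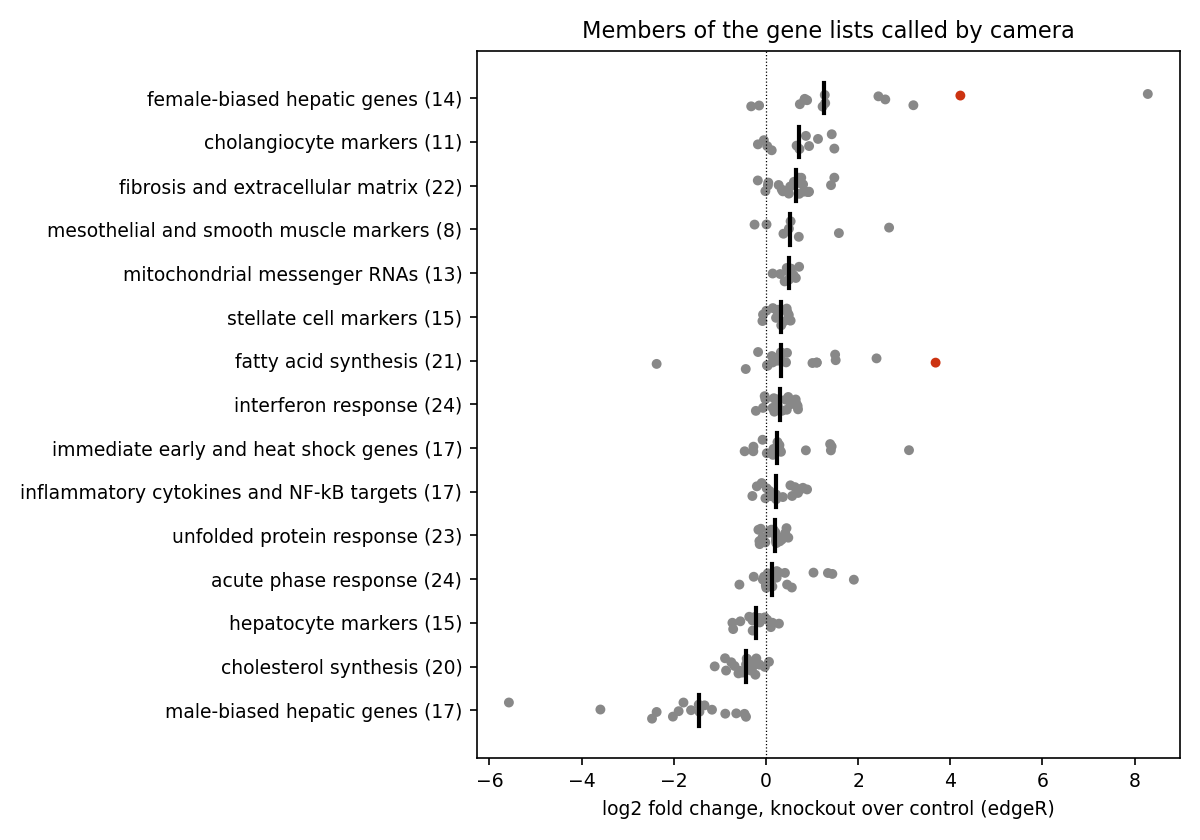
Log2 fold change, knockout over control (edgeR), of each tested member of the 15 gene lists called by camera, with the number of members in brackets; each point is 1 gene, red where the gene passed edgeR's test over all genes, and the black bar is the median. Medians ran from -1.46 for male-biased hepatic genes to 1.25 for female-biased ones.

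Of the 44 lists tested, camera called 12 higher and 3 lower with its preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.781. In the simulation, an estimated correlation called 0 of 5 shifted lists. A call lost with it therefore does not show that a list did not move. The female-biased and acute phase lists lost their calls although their estimated correlations (-0.046 and -0.028) lay below the preset 0.01. Fry called 0, with a smallest adjusted p of 0.584. The libraries numbered 4 against those numbered 3 gave 16 called lists, and the remaining way to pair the 4 libraries gave 15. Among the lists not called were LXR targets (adjusted p = 0.0653), pericentral and periportal genes (adjusted p = 0.112 and 0.129), bile acid synthesis (adjusted p = 0.174), the proteasome (adjusted p = 0.128), the circadian clock (adjusted p = 0.979) and oxidative phosphorylation (adjusted p = 0.854). Lists of neutrophil markers, pancreas and gut markers, and the sex-linked genes kept fewer than 5 tested members and were not tested.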

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

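The non-legacy and robust edgeR fits, and the comparison of all ways to pair the libraries, were chosen only after the results were seen. Cyp2a4 and Pnpla3 were called in all 16 alternative fits across genes. edgeR called 2 genes higher and 0 lower (242 higher and 214 lower at an unadjusted p under 0.05, together below a share of 0.05). The number lower was 1 with no low-count filter, 1 without X and Y genes, 1 with the non-legacy fit and 1 with the robust fit. DESeq2 called 23 higher and 19 lower, and limma-voom 3 and 0. Leaving out 1 library gave from 6 higher (without knockout 4) to 58 higher (without control 3) and from 0 lower (without knockout 4) to 47 lower (without control 4). In those fits the lone library of a group was assumed to vary like the other group, and the cause was not tested. March6 kept its direction in every alternative, and passed with DESeq2 (log2 fold change -1.55, adjusted p = 0.000128) and with the library number as a block (-1.568, adjusted p = 0.000509). Its adjusted p in the other alternatives ranged from 0.0548 to 0.482, and its log2 fold change without 1 library from -1.69 to -1.43.

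Only a number is shared between groups, and no label says that it marks a litter or a day. Across genes, the difference of 3 against 4 in control correlated with that in knockout (r = 0.364; genes are not independent replicates). With the number as a block, 59 genes were called higher and 84 lower, 41 of them among the 42 that DESeq2 called, and 13 lists higher and 3 lower. Calls of the other ways to split the 4 libraries bear on all of these counts. In 2 of the 3 splits at least 2 genes were called, 2 in the real one and 14 in the highest other, which set number 4 against 3 and had 2091 genes at an unadjusted p under 0.05 against 456, a structure of the samples by number. In 3 of 3 splits at least 15 lists were called, 15 in the real one and 16 in the highest other. With 3 splits the share cannot be under 0.05.

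Of the list calls, 12 higher and 3 lower, 0 higher and 0 lower were left with an estimated correlation, and 0 and 0 with fry. The estimated correlation had also called 0 of the 5 shifted lists in the simulation. The filter of at least 50 counts gave 9 higher and 6 lower, and kept fewer than 5 mesothelial markers, so that this list was not tested. Leaving out 1 library gave 5 to 18 lists higher and 3 to 9 lower, with 5 higher and 9 lower both without knockout 3. The male-biased, female-biased and matrix lists were called in each leave-one-out fit, with medians from -3.406 to -0.7938, 1.297 to 1.796 and 0.3937 to 1.015.

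The median of cholesterol synthesis, Sqle and Hmgcs1 changed sign when control 3 or knockout 4 was left out, the high library of one group and the low library of the other, and Mvk and Dhcr7 changed sign without control 3. Either omission leaves the numbers uneven between the groups. Part of the 3-against-4 difference (list medians 1.26 in control and 1.36 in knockout) then enters the fold change. With all 4 libraries and the number as a block, the list median was -0.4792. Without 1 library, the median of cholesterol synthesis ranged from -1.309 to 0.17, Sqle from -2.32 to 0.32, Hmgcs1 from -1.43 to 0.42, Mvk from -1.58 to 0.18 and Dhcr7 from -0.73 to 0.0138 (log2 fold changes). Other genes also changed sign, among them genes near 0 in the main fit. Dgat2 ranged from -0.48 to 0.41 (-0.0279 with limma-voom and -0.033 with the block), Plin2 from -0.28 to 0.54, Mttp from -0.18 to 0.0839, Cpt1a from -0.46 to 0.0236, Hspa5 from -0.0488 to 0.44 and Ddit3 from -0.38 to 0.64. Lcn2 and Egr1 were not near 0 in the main fit (log2 fold changes 1.35 and 1.43), and ranged from -0.10 to 2.07 and from -0.22 to 2.19. Lcn2 had 16.7 CPM in knockout 3 and 74.7 in knockout 4, and Egr1 26.4 and 4.95. Eif2s3y ranged from -0.17 to 0.14, Kdm5d from -0.30 to 0.13 and Uty from -0.24 to 0.11. The median of immediate early and heat shock genes ranged from -0.17 to 0.57. That of hepatocyte markers ranged from -0.52 to -0.0188, where camera's direction turned without knockout 4. Outside cholesterol synthesis, the cause of these changes was not tested beyond the library left out. Scaling by DESeq2 size factors or upper quartile changed no direction of a named gene, and ended 1 call, that of the hepatocyte list with DESeq2 size factors.

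Depth limited the transcripts near 0. In knockout, a count of 0 over both libraries still allows 3 counts. The median standard error of a log2 fold change was 0.305.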

Other observations

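The tests on brain tissue, nerve fibres, deeper sequencing, female RNA, the numbers in female-biased genes and the mitochondrial share were chosen only after the results were seen, as were the other ways to split the libraries and the single genes named here.

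Slc22a27, Slc22a26, H2-Q1 and Dusp1 were among the genes that DESeq2 called higher and edgeR did not. Slc22a27 and Slc22a26, of the family of organic ion transporters, had 4.38 ± 1 against 31.6 ± 19.1 CPM and 3.45 ± 1.82 against 19.5 ± 10.8 CPM (SD, n = 2 each; DESeq2 adjusted p = 1.6e-07 and 0.000259). H2-Q1, a class I histocompatibility gene, had 6.08 ± 1.1 against 28.1 ± 20.2 CPM (DESeq2 adjusted p = 0.00159, edgeR adjusted p = 0.502; log2 fold change from 1.187 to 2.815 without 1 library). Dusp1, a phosphatase induced by stress and glucocorticoids, had 39.2 ± 12.9 against 104 ± 37.3 CPM (DESeq2 adjusted p = 0.0269, edgeR adjusted p = 0.725). Adgrd1, an adhesion receptor, had 0 counts in both control libraries and 17 and 18 in the knockout libraries, and was the 1 gene of that kind, against 14 genes with 0 counts in both knockout libraries and at least 10 in each control.

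Male-biased genes were lower in knockout 4 than in knockout 3 (median log2 difference of 3 minus 4, 2.342), while the median of female-biased genes was higher in knockout 3 (0.3797). The 4 female-biased genes called when adjusted over their list alone went the other way, with 79.8 CPM in knockout 3 and 99.1 in knockout 4 for Cyp2a4, 346 and 926 for Cyp2b9, 281 and 888 for Cyp2a22 and 2.17 and 85.4 for Cyp2b13. In control the medians of 3 minus 4 were 0.6257 for male-biased and -0.4748 for female-biased genes. Of the 17 male-biased genes, 15 were higher in the library numbered 3 in both groups, so that split is not particular to the knockout. Serpina1e had 2736 and 5109 CPM in control, 620 CPM in knockout 3 and 30.9 CPM in knockout 4. Cyp2b13 had 0.159 and 0.108 CPM in control. Sult2a5, a sulfotransferase gene, had 0 counts in the other 3 libraries and 578 in knockout 4, and its call by DESeq2 rests on that library.

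The shift of male-biased genes downward and female-biased genes upward may come from a change in the hepatocytes of the knockout, which these tests do not show. A female animal or female RNA among the knockout libraries is argued against, since the smaller Y-linked sum of the knockout libraries was 0.91 of the control mean and Xist had at most 6 counts. For male-biased genes, reads shared within the Mup and Cyp families do not account for the whole fall. The 9 male-biased genes outside these families had a median log2 fold change of -1.44. Among them was Serpina1e, which has relatives such as Serpina1a and Serpina1c, so sharing within other families is not excluded. Each group holds a library of each number, so a difference between the numbers alone could not produce a fall in the knockout. That 100% of male-biased genes were lower in the knockout library of both numbers shows only that both pairs had the fall. These genes move together (estimated correlation 0.753), so they are not independent evidence. Of the female-biased genes, 10 of 14 (71.4%) were higher in the knockout library of both numbers. This is short of the 80% asked of male-biased genes, so that comparison was undecided by its bound, and not all members had the rise in both pairs. The balance of numbers holds here too, so a difference between the numbers alone could not produce a rise in the knockout. With the preset correlation, the female-biased list was called with the number as a block and without it (camera adjusted p = 1.671e-10 and 2.58e-07). With an estimated correlation, fitted without the block, the list was not called (camera adjusted p = 0.781). Hormone state, litter and age of the mice, which could act on these genes together in 2 animals, stay open and untested.

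Some nervous transcripts were counted in both control libraries and nearly missing from both knockout libraries, while other neuron markers were present in all 4. Deeper sequencing of the controls is argued against by a ratio of total counts of 0.885. A loss of liver nerve fibres cannot be told apart, because the peripheral nerve markers lay near the floor: 9 had a count, 7 of them higher in control, 1 reached 1 CPM in a library, and their summed counts were 1.07 times as high in control (95% interval 0.776 to 1.47). RNA or reads of brain tissue in the controls stay a candidate explanation that cannot be told apart either. Of markers with a count, 10 of 14 of astrocytes (71.4%) and 8 of 13 of oligodendrocytes (61.5%) were higher in control, and several of these have a level in liver that would hide a small share. The abundant myelin gene Mbp had 37 and 33 counts in control and 21 and 26 in knockout. Islet and neuroendocrine markers, 6 of 6 higher in control, summed to 17 and 8 counts against 0 and 3.

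The sterol genes split by library number, in both groups. A difference in RNA make-up that follows the mitochondrial share is argued against, since that share was higher in control 3 than in control 4 by 6.92 percentage points, while knockout 3 minus knockout 4 was -11.8. Different collection times after refeeding could do this and cannot be told apart here: over 22 clock genes the differences of 3 against 4 in the groups correlated at 0.306, at the 33.9th percentile of 10000 random lists matched on expression (median 0.425). The bound set beforehand, below that median, was too loose to exclude it, because the value lies well inside the spread of the random lists. Differences in food intake or batch between the numbers were not tested.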
